A study of Mus musculus with 6 samples.

How the data were processed

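Total RNA from remnant liver of C57Bl/6 mice was measured 12 h after surgical removal of 70% of the liver (partial hepatectomy, a standard model of liver regeneration). The series holds 6 one-channel Affymetrix arrays, 3 from wildtype mice and 3 from mice with a hepatocyte-specific knockout of Klf6, labelled DeltaKlf6; per the labels each array is 1 animal, out of 6 animals per group in the overall study. RNA was extracted with TRIzol, purified on RNeasy columns and labelled with a 3' IVT Express kit, per the labels' protocols. Groups and replicate numbers were taken from the sample labels.

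The deposited values are log2 expression values made by the authors with RMA (background correction, quantile normalization and a median-polish summary per probe set) in Affymetrix Expression Console 1.2.1, per the submitters' processing notes. The log base is not written in the table and was inferred: the highest value was 13.9, under the limit of 16 that a 16-bit scanner sets on the log2 scale, and a natural or decimal log of that size would exceed the scanner's range. The genome build and probe annotation the authors used are not given in the sources used here, so no coordinates are given. The table held 45141 probe sets in 6 columns, all of which matched a sample, and included 104 control probe sets.

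Probe sets were named from the platform annotation, in which 28898 had a single gene symbol, 551 had several and 15692 had none here. Symbols were checked against RefSeq through the Entrez gene number, which changed 0 of them. Each of 17097 genes was represented by its probe set with the highest mean over the 6 arrays, and no gene was named from a probe set with several genes. Probe sets of 1 gene that disagreed in sign are pointed out beside the gene.

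DeltaKlf6 was compared with wildtype with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with statmod 1.5.0 for the robust option), with genotype as the factor in the model and Benjamini-Hochberg adjustment over all genes; the threshold was an adjusted p of 0.05. Klf6 was tested on each of its probe sets. A total of 34 gene lists covering liver functions, stress responses, proliferation, autophagy and the cell types of liver was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Of 589 list entries 515 were measured, 1 of them found through an older symbol, and these were 508 distinct genes, since a few genes stand in more than 1 list. Means and medians over a list's members are of log2 differences, DeltaKlf6 minus wildtype. Tests were two-sided.

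The comparison, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Klf6, then up to 10 genes per direction past the threshold with non-overlapping groups; where fewer pass, each direction is filled to 10 with the genes of smallest unadjusted p among those with non-overlapping groups and at least a 1.5-fold difference, described as values that did not pass; and up to 4 members per list with the smallest unadjusted p. Placeholder symbols were counted but not named. Other genes named in the text were chosen after their values were seen, which is said where they appear.

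The calculations were tested on simulated data for this comparison. With 17097 simulated genes at the spread of the deposited arrays, 16% of 50 genes changed by a log2 size of 1 were recovered at the adjusted threshold, 92% of those changed by 2, and 100% of those changed by 3 or 4, with 8 of 16897 unchanged genes called. At the wildtype spread alone the recovered share at a log2 size of 1 was 66%. The simulated genes varied independently, with the same spread in both groups and 50 changed genes at each size. In the deposited arrays list members were correlated and the median gene SD in DeltaKlf6 was 1.47 times that in wildtype. The recovered shares therefore check the calculation and do not give the power of the real comparison. In 50 simulated sets the members of each list shared an array effect (SD 0.5), with no genotype effect. There camera at the preset correlation called a mean of 18.6 of the 34 lists per set, and 0.04 with the correlation estimated per list. Both results are therefore given for each list that passed. In the wildtype arrays the real list means spanned -0.10 to 0.06 for fatty acid oxidation and PPARA targets and -0.29 to 0.56 for G1 and S phase. Recovery of a shifted list was simulated at the preset correlation only. A call lost with an estimated correlation therefore does not show that a list is unchanged.

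Alternatives were the mean of a gene's probe sets, separate tests of every probe set, probe sets shared between transcripts left out, dim genes left out, arrays quantile-normalized or median-centred again, a variance trend, robust variances, array weights, the replicate number as a block, each array left out in turn, a minimum fold of 1.5 and an unmoderated pooled-variance test; for lists also an estimated correlation, ranks and the self-contained test fry. An array holds no counts, so precision is limited by the number of arrays. The raw scanner files were not analysed here, so background and detection per probe set could not be reassessed.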

Results

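Liver expression was measured 12 h after 70% partial hepatectomy in 3 wildtype mice and 3 mice with a hepatocyte-specific Klf6 knockout. The question was which transcripts in the regenerating liver depend on hepatocyte Klf6, a zinc-finger transcription factor. Each array gave 45141 log2 values with medians between 3.30 and 3.45. All 6 animals had the male pattern, with Eif2s3y, a Y-linked gene, between 7.77 and 8.53 and Xist between 2.61 and 3.30. The wildtype arrays correlated with each other across genes at 0.982 to 0.983 and the DeltaKlf6 arrays at 0.946 to 0.964. Across the groups the closest pair was wildtype 2 with DeltaKlf6 2, at 0.981 (root mean square log2 difference 0.486), close to the wildtype pairs (0.451 to 0.475).

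Klf6 itself was not uniformly low in the knockout group. The 3 Klf6 probe sets were at 3.68 ± 0.31, 4.06 ± 0.36 and 4.91 ± 0.41 in wildtype (mean ± SD, n = 3) and at 3.82 ± 1.73, 4.58 ± 1.14 and 4.93 ± 1.96 in DeltaKlf6 (n = 3). In the library labelled DeltaKlf6 1 all 3 Klf6 probe sets lay above every wildtype array, by 2.13, 1.82 and 2.12 over the wildtype mean. In the library labelled DeltaKlf6 2 they differed from the wildtype mean by -0.87, 0.05 and -0.30, and in the library labelled DeltaKlf6 3 by -0.86, -0.32 and -1.75. The group differences were 0.13, 0.52 and 0.02 with standard errors of 0.74, 0.52 and 0.84, and none passed the test (adjusted p = 0.998, 0.996 and 0.999). Without the library labelled DeltaKlf6 1 the differences were -0.86, -0.13 and -1.03. Where these probe sets lie relative to the deleted part of Klf6 is not known here, and a probe set outside that part checks nothing. The first 2 wildtype means are close to the array medians, and detection was not assessed, so a loss of Klf6 has little room to show there. Whole liver also holds cells other than hepatocytes. Since Klf6 went against the label in 1 library, every direction below is between libraries as labelled.

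**Figure D1:**
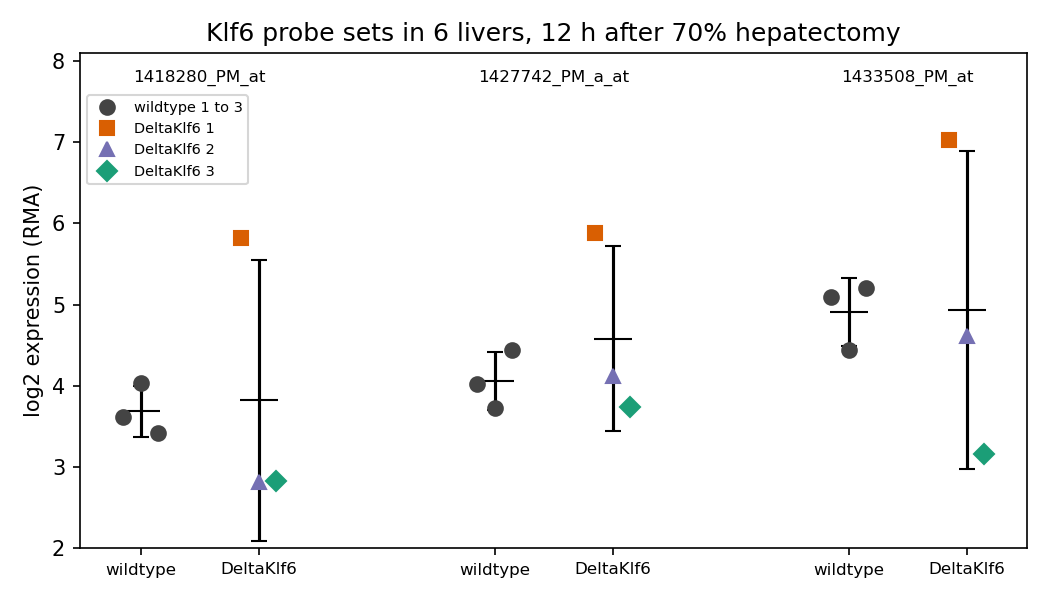
Klf6 log2 expression (y axis, RMA) for each of the 3 Klf6 probe sets (panels along the x axis) in wildtype and DeltaKlf6 livers; points are single arrays, horizontal bars the group means and whiskers the SD (n = 3). The library labelled DeltaKlf6 1 lies above all wildtype arrays in all 3 probe sets.

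No single gene passed the test between libraries labelled DeltaKlf6 and wildtype. On the lower side, Ppara, the nuclear receptor that drives fatty acid oxidation, was at 9.05 ± 0.19 in wildtype and 7.44 ± 0.59 in DeltaKlf6 (log2 difference -1.61, SE 0.31). The acyl-CoA thioesterases Acot1 and Acot3 differed by -1.91 (SE 0.38) and -2.51 (SE 0.46). The 1 probe set of Acot3 is of the type shared between transcripts. Fitm2, a lipid droplet protein, differed by -1.14 (SE 0.22) and Hlf, a clock-controlled transcription factor, by -1.60 (SE 0.32). The macrophage scavenger receptor Cd163 was at 6.48 ± 0.27 in wildtype and 5.30 ± 0.16 in DeltaKlf6 (-1.17, SE 0.23). N4bp2l1 (-1.25), Plce1 (-1.07), Asic5 (-1.90) and Celf2 (-1.01) completed the 10 lower genes. On the higher side stood Ccne1, encoding cyclin E1, at 5.38 ± 0.30 in wildtype and 6.54 ± 0.27 in DeltaKlf6 (1.16, SE 0.25). Mnat1, a subunit of the CDK-activating kinase, differed by 1.17 (SE 0.26) and the acute phase gene Orm3 by 1.80 (SE 0.39).

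The other higher genes were Ugt2b37 (log2 difference 0.99), Sccpdh (1.03), Ripk3, a kinase of necroptosis (0.93), Nol3 (1.05), Vps45 (0.96), Psrc1 (0.82) and Borcs8 (0.91). Nol3 had this sign in 1 of its 3 probe sets and Borcs8 in 1 of 2. The wildtype means of Ripk3 (2.63), Nol3 (2.96) and Sccpdh (3.03) lay under the array medians. Those of Psrc1 (3.65) and Ugt2b37 (3.68) lay close to them, and detection was not assessed, so these differences may be among background signals. All 20 had non-overlapping groups of 3 arrays, and all had an adjusted p of 0.992, so these are values that did not pass. By limma 0 genes were higher and 0 lower at an adjusted p under 0.05 among 17097. At an unadjusted p under 0.05 there were 631 (207 higher, 424 lower), where chance alone gives 855. Groups did not overlap for 1594 genes (9.32%), where chance gives 10%. The count at an unadjusted p under 0.05 was 1546 without the library labelled DeltaKlf6 3, 1165 without DeltaKlf6 2, 388 without wildtype 1 and 379 without wildtype 3, again with 0 genes past adjustment in each.

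The mean of the genes of fatty acid oxidation and PPARA targets was lower in every library labelled DeltaKlf6. Of 18 measured members 17 were lower by group mean and 1 was higher, 5 were lower in all 3 libraries, and the groups did not overlap for 4. The list had a mean log2 difference of -0.66 and a median of -0.44 (camera adjusted p = 2.19e-06; adjusted p = 0.145 with an estimated correlation; fry adjusted p = 0.0173). The list mean was -0.71, -0.56 and -0.72 in the libraries labelled DeltaKlf6 1, 2 and 3, against -0.10 to 0.06 in the wildtype arrays. All 3 DeltaKlf6 means also lay below the wildtype arrays for female-biased genes (-0.54, -0.36 and -0.51, lowest wildtype array -0.16). With a narrow margin in at least 1 library, the same held for fatty acid and triglyceride synthesis (-0.072, -0.28 and -0.34, lowest wildtype array -0.069). It held as narrowly for unfolded protein genes (-0.103, -0.099 and -0.232, lowest wildtype array -0.090). The erythroid mean lay above the wildtype arrays in all 3 (0.14, 0.17 and 0.31, highest wildtype array 0.02). These lists did not pass. No member passed adjustment over all genes, and 4 passed when adjusted over the list alone: Ppara, Acot1, Ehhadh, a peroxisomal oxidation enzyme (-1.03, SE 0.28), and Cpt1a, which admits long-chain fatty acids to mitochondria (-0.82, SE 0.25). The hepatokine gene Fgf21 (-1.22, SE 0.56), Vnn1 (-1.34, SE 0.68) and Cyp4a10 (-1.17, SE 0.62), named after their values were seen, did not pass over the list.

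**Figure D2:**
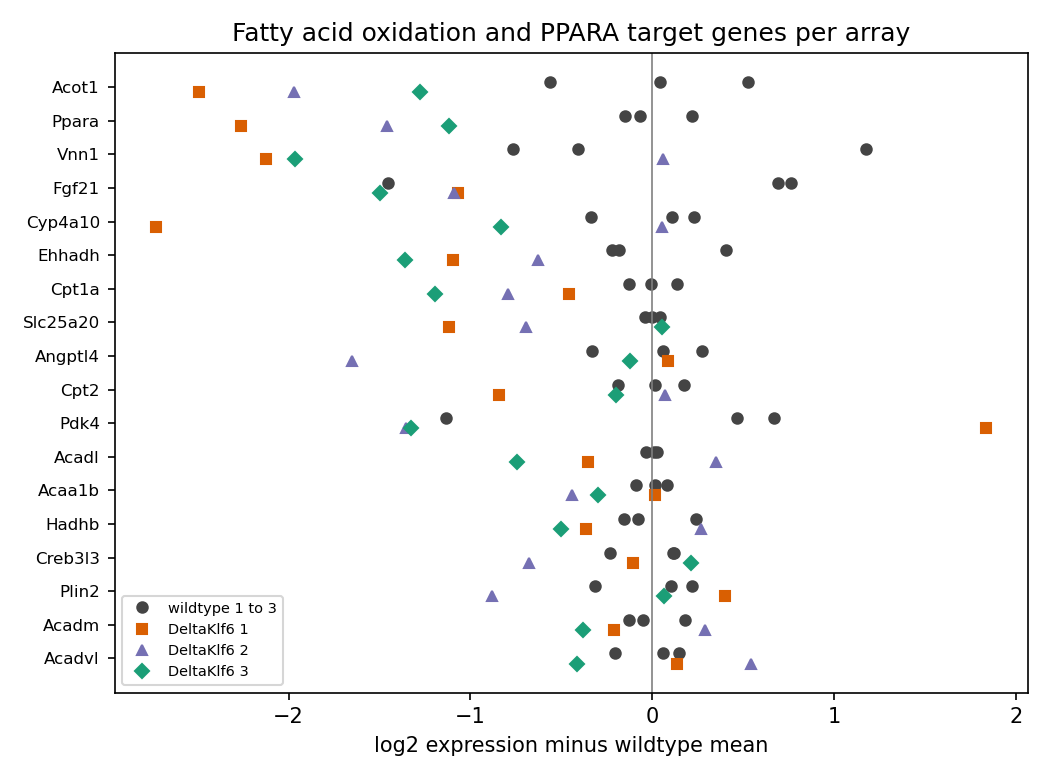
Log2 expression minus the wildtype mean (x axis) of the 18 measured fatty acid oxidation and PPARA target genes (y axis) in each of the 6 arrays; grey points are wildtype arrays and coloured points the libraries labelled DeltaKlf6. Acot1, Ppara, Ehhadh and Cpt1a lie below all wildtype arrays in each of the 3 DeltaKlf6 libraries, and Pdk4 lies high in DeltaKlf6 1.

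The proliferation lists were higher on average, most of all in the library labelled DeltaKlf6 2. Of 28 genes of G1 and S phase 25 were higher (mean 0.44, median 0.41, camera adjusted p = 0.00019; adjusted p = 0.640 with an estimated correlation), and of 21 genes of G2 and mitosis 20 were higher (mean 0.54, median 0.49, camera adjusted p = 3.48e-06; adjusted p = 0.640 with an estimated correlation). List means in the libraries labelled DeltaKlf6 1, 2 and 3 were -0.18, 1.49 and 0.01 for G1 and S phase and 0.01, 1.48 and 0.13 for G2 and mitosis. In wildtype 1, 2 and 3 they were -0.26, 0.56 and -0.29 for G1 and S phase, so that wildtype 2 lay above DeltaKlf6 1 and 3, and -0.23, 0.08 and 0.15 for G2 and mitosis. Without DeltaKlf6 2 the group means were -0.08 (adjusted p = 0.944) and 0.07 (adjusted p = 0.381). The G1 and S mean was 0.75 without DeltaKlf6 1 and 0.72 without wildtype 2. Single genes were higher in all 3 libraries, 4 of the G1 and S list and 11 of the G2 and mitosis list, and the groups did not overlap for 3 and 2 genes of these lists. Ccne1 was at 1.47, 1.05 and 0.96 above wildtype and Plk1 at 0.70, 0.82 and 0.51. Ccne1 was the 1 member past the threshold when adjusted over the list alone. Chaf1b (0.64), Pole (0.96) and Cdk4 (0.38) in the first list and Plk1 (0.68), Cenpe (0.58), Aurka (0.87) and Nusap1 (1.10) in the other did not pass.

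Immediate early genes, NRF2 targets and p53 targets were higher on average, most of all in the library labelled DeltaKlf6 1, in which Klf6 was also high. The immediate early list had 15 of 17 members higher (mean 0.39, camera adjusted p = 0.00789, and 0.640 with an estimated correlation). Its members of smallest unadjusted p, not of largest difference, were Junb (0.86), Egr1 (1.11), Dusp1 (0.92) and Fosb (0.29). NRF2 targets, the oxidative stress genes, had 13 of 16 higher (mean 0.36, adjusted p = 0.00914, and 0.640 with an estimated correlation). By the same rule Cbr3 (0.81), Gstm3 (0.72), Ephx1 (0.59) and Srxn1 (0.73) are named. The p53 targets had 14 of 20 higher (mean 0.31, adjusted p = 0.0144, and 0.640 with an estimated correlation). Here the rule names Eda2r (0.82), Gadd45a (1.37), Pmaip1 (0.63) and Ccng1 (0.36). No member of these lists passed over all genes or over its list.

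In the library labelled DeltaKlf6 1 the means of the immediate early, NRF2 and p53 lists were 1.15, 1.05 and 0.92 above wildtype. The NRF2 mean was 0.41 in DeltaKlf6 2 and -0.39 in DeltaKlf6 3, opposite signs that cancel between these libraries. Without DeltaKlf6 1 the group means were 0.01, 0.01 and 0.00 (adjusted p = 0.847, 0.768 and 0.847). The p53 list also lost its call without wildtype 1 (mean 0.24, adjusted p = 0.0514) and without wildtype 2 (0.32, adjusted p = 0.0511), and the NRF2 list without wildtype 3 (0.29, adjusted p = 0.0527). Without DeltaKlf6 3 the immediate early, NRF2 and p53 means were 0.62, 0.73 and 0.47. In all, 6 of 34 lists passed camera at the preset correlation, 0 with an estimated correlation and 1 by fry, the PPARA list. Without DeltaKlf6 3 the number was 11.

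**Figure D3:**
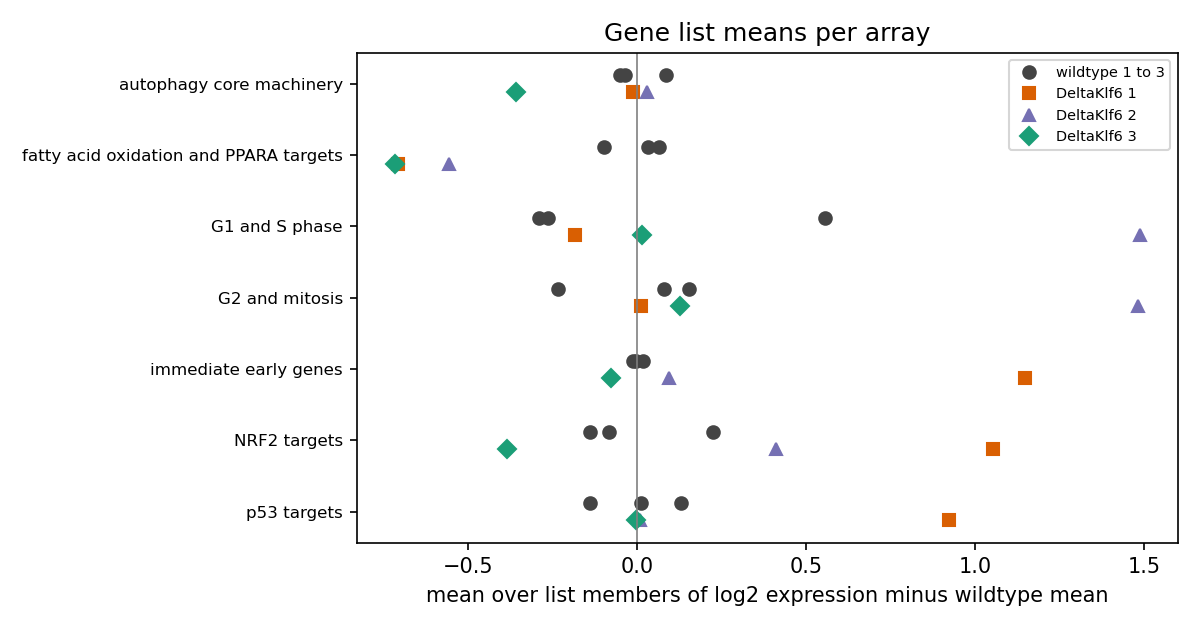
Mean over list members of log2 expression minus the wildtype mean (x axis) for the 6 lists past the camera threshold and the autophagy core list (y axis), 1 point per array; grey points are wildtype arrays. Among the lists shown, the fatty acid oxidation and PPARA list alone has all 3 libraries labelled DeltaKlf6 (-0.71, -0.56 and -0.72) below the wildtype arrays.

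Autophagy genes, tested because Klf6 has been linked to autophagy in the liver, did not pass as a list. Of 28 core genes 7 were higher and 21 lower (mean -0.11, adjusted p = 0.179), with 0 past the threshold over all genes or over the list. Atg9a (-0.61, SE 0.26), Atg10 (-0.63, SE 0.29) and Atg14 (-0.46, SE 0.23) were lower and Gabarapl2 (0.56, SE 0.29) higher. The list mean was -0.36 in the library labelled DeltaKlf6 3 and -0.01 and 0.03 in DeltaKlf6 1 and 2, and without DeltaKlf6 3 it was 0.01. Becn1 differed by -0.23 and Atg7 by 0.00, named after their values were seen. Receptors and lysosomal genes had 10 of 19 higher (mean 0.01, adjusted p = 0.963), with Sgsh at -0.56 and the cathepsin gene Ctsl at 0.64. The other Klf genes had 10 of 13 lower (mean -0.18, adjusted p = 0.482), with Klf12 at -1.34.

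Other metabolic lists did not pass. Fatty acid and triglyceride synthesis had 11 of 17 lower (mean -0.23, adjusted p = 0.143), with the desaturase gene Fads2 at -1.19 and Acacb at -1.11. Cholesterol synthesis had 10 of 19 lower (mean 0.02 and median 0.00, adjusted p = 0.963, Stard4 -0.69, Lss -0.98). Glucose metabolism had 8 of 12 lower (mean -0.11, adjusted p = 0.661, Pygl 0.78). Bile acid synthesis and transport had 10 of 17 lower (mean -0.12, adjusted p = 0.988, Abcb11 0.62) and CAR and PXR targets 9 of 16 (mean -0.04, adjusted p = 0.988, Cyp2b10 0.82). The last pair had negative means and a camera direction upward. Circadian clock genes had 9 of 16 higher with a mean of -0.30 and a median of 0.06 (adjusted p = 0.179). Hlf passed when adjusted over the list alone, and Per3 (-1.76, SE 0.60), Per2 (-1.32, SE 0.51) and Tef (-1.10, SE 0.44) did not. Genes higher in male liver had 8 of 11 higher (mean 0.37, adjusted p = 0.0726, Selenbp2 0.73, Egfr 0.50). Genes higher in female liver had 8 of 10 lower (mean -0.47, median -0.17, adjusted p = 0.0552). Acot3 (-2.51) and Cyp17a1 (-1.57, SE 0.38) passed when adjusted over the list alone, and the mean rests largely on these genes. Without probe sets shared between transcripts, the type of Acot3, the female-biased mean was -0.25 (camera adjusted p = 0.241). The male-biased and female-biased lists were near the threshold and passed under some alternatives, among them a variance trend (adjusted p = 0.0289 for each). With an estimated correlation the adjusted p was 0.640 for each.

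Inflammation and protein stress lists did not pass either. The acute phase list had 14 of 23 higher (mean 0.09, adjusted p = 0.295), with Orm3 past the threshold when adjusted over the list alone and A2m at -1.77 (SE 0.66). The NF-kB and inflammatory cytokine list had 11 of 19 lower with a mean of 0.08 and a median of -0.10 (adjusted p = 0.685, Vcam1 0.97, Il1b -0.43). The interferon list had 10 of 20 higher with a mean of 0.05 and a median of -0.06 (adjusted p = 0.651, Ifit3 -0.58, Irf7 0.65). The unfolded protein and integrated stress list had 12 of 19 lower (mean -0.14, adjusted p = 0.317, Trib3 -0.52). The heat shock list had 6 of 9 lower (mean -0.20, adjusted p = 0.317, Hspa1b -0.81).

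No list of cell type markers passed the test with all 6 arrays at the settings fixed beforehand. Under alternatives some did, such as hepatocyte secreted proteins (adjusted p = 0.00875) and Kupffer cell markers (adjusted p = 0.0301) with array weights, and with an estimated correlation their adjusted p was 0.761 and 0.693. Pericentral hepatocyte markers had 10 of 12 higher (mean 0.18, adjusted p = 0.151, Lgr5 0.65). Periportal markers had 7 of 11 higher (mean 0.14, adjusted p = 0.317, Hal 0.97) and hepatocyte secreted proteins 10 of 13 (mean 0.16, adjusted p = 0.143, Serpinc1 0.53). Kupffer cell and macrophage markers had 10 of 14 higher (mean 0.17, adjusted p = 0.143) although Cd163 was lower and was the 1 member past the threshold when adjusted over the list alone. Mpeg1 (0.58) and C1qb (0.72) were higher. Stellate cell and fibroblast markers had 9 of 14 higher (mean 0.11, adjusted p = 0.272, Des 0.41). Sinusoidal endothelial markers had 9 of 15 lower (mean -0.12, adjusted p = 0.317, Kdr -0.87, Stab2 -0.61). Cholangiocyte markers had 5 of 6 higher (mean 0.14, adjusted p = 0.295, Sox9 0.48). Neutrophil markers had 5 of 10 higher (mean -0.04, adjusted p = 0.988) and lymphocyte markers 8 of 14 (mean 0.03, adjusted p = 0.988, Cd3g -0.46). Erythroid markers had 4 of 4 higher (mean 0.21, adjusted p = 0.179, Hba-a1 0.53) and pancreatic acinar markers 6 of 9 (mean 0.02, adjusted p = 0.902, Cel -0.54). Adipocyte markers had 0 of 5 higher (mean -0.27, adjusted p = 0.143, Fabp4 -0.47).

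All 3 libraries labelled DeltaKlf6 left the wildtype range in the hybridization and Gapdh controls, DeltaKlf6 1 and 2 on the lower side and DeltaKlf6 3 on the higher side. The hybridization controls were at 9.66, 9.66 and 11.02 in DeltaKlf6 1, 2 and 3, against 9.92 to 10.13 in wildtype. The 3'-minus-5' signal was 3.47, 3.45 and 4.83 for Gapdh, against 4.06 to 4.43 in wildtype. For actin it was 4.223, 3.998 and 5.049 in DeltaKlf6 1, 2 and 3, against 4.859 to 5.394 in wildtype. The DeltaKlf6 actin values differed from the wildtype mean by -0.87, -1.09 and -0.04. The 3' signal thus exceeded the 5' signal in all 6 arrays, and by less in DeltaKlf6 1 and 2 than in any wildtype array. The gap was large in wildtype too, at least 4.06 on the log2 scale, so a strong 3' bias may limit every comparison here. Wildtype is therefore a reference for differences only, and its own RNA quality was not assessed beyond these controls. The upper quartile of the values in DeltaKlf6 3 was 5.08, against 5.50 to 5.63 in the other 5 arrays, and the middle-minus-5' actin signal was 0.13, against 1.26 to 1.86. In this library the hepatocyte secreted list was at -0.28, the endothelial list at -0.39, cholesterol synthesis at -0.54 and bile acid genes at -0.75 relative to wildtype, beside -0.36 for autophagy core genes.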

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

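Tests of the splits of the arrays were planned before their results were seen; the other tests in this part were chosen only after the results were seen. Control probe sets outside the gene comparison left the wildtype range in all 3 libraries labelled DeltaKlf6. In DeltaKlf6 3 the following stood above the wildtype mean: the hybridization controls by 0.97, the 18S ribosomal RNA controls by 1.23 and the 3'-minus-5' Gapdh signal by 0.58 on the log2 scale, where the wildtype SDs were 0.11, 0.26 and 0.19. In DeltaKlf6 1 and 2 the hybridization controls stood at -0.39 and -0.39 and the 3'-minus-5' actin signal at -0.87 and -1.09 from the wildtype mean. The hybridization and Gapdh controls thus lie on opposite sides of wildtype within the DeltaKlf6 group. The 18S controls lay above the wildtype mean in all 3 libraries, by 0.38 and 0.29 in DeltaKlf6 1 and 2. The actin signal lay below it in all 3, at -0.04 in DeltaKlf6 3.

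The spread between arrays was larger in the DeltaKlf6 group, with a median gene SD of 0.352 against 0.240 in wildtype, a ratio of 1.47. The quality of the library labelled DeltaKlf6 3 is not its whole cause, since DeltaKlf6 1 and 2 differed by 0.678 (root mean square log2 difference) where the largest wildtype pair differed by 0.475. The real split had the ratio farthest from 1 (1 of 10 splits, the highest other being 1.40), but 10 splits are too few for a share under 0.05. A genotype effect that varies between animals stays open and may be as good an account as animal, handling or array quality differences, DeltaKlf6 1 and 2 included, which were not tested.

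In the library labelled DeltaKlf6 1 Klf6 was high. Noise of a single probe set is argued against by the lowest of the 3 excesses, 1.82, which lies far beyond the wildtype SDs of 0.31 to 0.41. An immediate early response in that animal is a candidate explanation: the immediate early list stood at 1.15 there and at most at 0.09 in the other 5 arrays. Whether this is a wildtype library under a DeltaKlf6 label cannot be decided. Its highest correlation with a wildtype array, 0.968, was under the 0.982 of the least similar wildtype pair. Its Klf6 lay above every wildtype array, so it departs from wildtype in both. A wildtype animal with an immediate early response of its own might depart too, which was not tested. The Klf6 level gives no sign of deletion, but where the probe sets lie relative to the deleted part is not known. No gene passed the test between the genotypes, which includes this array, so none marks the genotype. DeltaKlf6 2 correlated with wildtype 2 at 0.981 but with wildtype 1 and 3 at 0.972 and 0.972, outside the wildtype pairs, and a wrong label there was not tested.

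The PPARA list was lower in all 3 libraries labelled DeltaKlf6. A lower share of hepatocyte RNA as the whole cause is argued against by the hepatocyte secreted list, at 0.27 and 0.48 in DeltaKlf6 1 and 2 (group mean 0.16) where the PPARA list was at -0.71 and -0.56, but at -0.28 in DeltaKlf6 3 a part there stays open. The quality of DeltaKlf6 3 is argued against by the PPARA mean without it, -0.63, with DeltaKlf6 1 and 2 both below every wildtype array. A shifted clock phase may contribute and cannot be told apart: clock outputs minus activators stood at -0.77, -3.73 and -0.80 in DeltaKlf6 1, 2 and 3, of which only DeltaKlf6 2 lay beyond 2 wildtype SDs (SD 0.61), and its PPARA list was the least low. The real split gave the smallest fry p for this list, 0.000509 (1 of 10 splits, the next being 0.310). The list stood out as the 1 list past fry in the real split, so its first place there carries little weight. The smallest fry p over all lists was not compared between splits, and 10 splits are too few for a share under 0.05. Genotype stays open, with Klf6 high in 1 of these libraries. The control differences of DeltaKlf6 1 and 2 also stay open, since their effect on this list was not tested.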

How the results depend on the processing

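Alternatives in this part were planned before the data were examined. Of 1112 alternative values 1004 kept their direction and their side of the threshold, 31 lost a call or gave a count over 1.5 times smaller, 30 gained a call or gave a count over 1.5 times larger, and 47 turned direction, 1 of them with a test past the threshold in either setting. All 354 alternative values of the 20 genes named by the rule kept their sign. With single arrays left out this was bound to hold, since the rule required non-overlapping groups. Settings that change only the variance or the threshold leave the difference itself as it was. No conclusion is drawn from these signs. In each setting that tested genes, 0 genes were higher and 0 lower at an adjusted p under 0.05. Except where stated, the cause was not tested.

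The count at an unadjusted p under 0.05 was 1620 with every probe set tested (more tests), 331 with the dim genes left out (fewer genes) and 379 to 1546 with single arrays left out. With the replicate block it was 703, and 8 lists passed, with a camera adjusted p of 1.40e-07 for G1 and S. Pairs of arrays with the same number had correlated deviations of 0.00, 0.26 and 0.08, and not every array correlated best with its own number, so the numbers are not read as pairs. The highest value, 0.26, was that of wildtype 2 with DeltaKlf6 2, the closest pair across the groups, so a factor shared by these arrays stays open. Lists past the threshold numbered 0 with an estimated correlation, 1 by fry, 0 by fry's mixed test, and 4 to 11 with single arrays left out. Those calls ended for the means of p53 (0.31), immediate early (0.39), G1 and S (0.44), G2 and mitosis (0.54) and NRF2 (0.36) with an estimated correlation and both fry tests, and for PPARA (-0.66) with an estimated correlation (adjusted p = 0.145) and the mixed test (0.0544). The estimated correlation was 0.31 to 0.64 for p53, immediate early, G1 and S, G2 and mitosis and NRF2. For PPARA it was -0.03, under the preset 0.01, so its lost call does not come from members more correlated than the preset. Its unadjusted camera p was 6.43e-08 at the preset and 0.00426 with the estimate. That change comes from another difference between the 2 forms of camera, which was not examined. Over the other alternatives the PPARA adjusted p was 7.68e-10 to 0.0173. With dim genes left out the p53 mean was 0.21 (adjusted p = 0.0781).

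Lists that had not passed gained a call as follows, with adjusted p in parentheses. None of them passed with an estimated correlation or by fry. Female-biased genes (mean -0.47) did so without dim genes (mean -1.41, 0.00172), after quantile normalization (0.0450), with a variance trend (0.0289), with the replicate block (0.0499) and without wildtype 3 (0.0156). Their mean was nearer 0 without shared probe sets (-0.25, 0.241) and with every probe set tested (-0.27, 0.384). Male-biased genes (mean 0.37) did so with the mean of probe sets (0.0324), every probe set (0.0210), dim genes left out (0.0414), a variance trend (0.0289), array weights (0.0154), the replicate block (0.0374), and without wildtype 2 (0.0312) or DeltaKlf6 3 (0.0235), while the mean was 0.11 without DeltaKlf6 2. Among cell types, Kupffer cell markers passed after quantile normalization (0.0450), with array weights (0.0301) and without DeltaKlf6 3 (0.0234), and hepatocyte secreted proteins with array weights (0.00875) and without DeltaKlf6 3 (0.000678). Stellate markers passed without DeltaKlf6 3 (0.0123), pericentral markers without wildtype 2 (0.0312) and adipocyte markers without wildtype 3 (0.0222). Clock genes passed with every probe set (0.0232) and without DeltaKlf6 1 (0.0337), as did the Klf family (0.00105) and fatty acid and triglyceride synthesis (0.0357) without that array, and cholesterol synthesis without DeltaKlf6 3 (0.0348).

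Leaving out single arrays moved the 3 Klf6 differences over -0.86 to 0.64, -0.13 to 0.94 and -1.03 to 0.91, and the third was -0.057 after quantile normalization. It moved list means over 0.0034 to 0.47 (p53), 0.0091 to 0.62 (immediate early), -0.084 to 0.75 (G1 and S), 0.069 to 0.80 (G2 and mitosis), 0.012 to 0.73 (NRF2) and -0.19 to 0.0084 (autophagy core). Means of lists that had not passed moved over -0.12 to 0.18 (autophagy receptors), -0.47 to 0.11 (Klf family), -0.051 to 0.20 (interferon), -0.20 to 0.29 (cholesterol), -0.44 to 0.19 (bile acids), -0.13 to 0.080 (CAR and PXR), -0.035 to 0.32 (pericentral) and -0.0011 to 0.38 (secreted). It also moved them over -0.039 to 0.33 (Kupffer), -0.16 to 0.13 (neutrophil), -0.060 to 0.36 (stellate), -0.23 to 0.011 (endothelial), -0.0040 to 0.32 (cholangiocyte), -0.041 to 0.098 (lymphocyte) and -0.071 to 0.11 (acinar). Means that kept their sign moved over -0.40 to -0.046 (heat shock), -0.51 to -0.13 (clock), -0.38 to -0.12 (adipocyte), -0.21 to -0.031 (glucose), 0.021 to 0.16 (NF-kB), 0.031 to 0.13 (acute phase), 0.087 to 0.24 (periportal), 0.11 to 0.63 (male-biased), -0.55 to -0.32 (female-biased), -0.31 to -0.18 (fatty acid and triglyceride synthesis), -0.19 to -0.092 (unfolded protein), 0.15 to 0.24 (erythroid) and -0.71 to -0.63 (PPARA). List means near 0 also turned to -0.014 (cholesterol, mean of probe sets). They turned to 0.0027 (Klf family), -0.11 (cholesterol), 0.027 (bile acids) and 0.081 (CAR and PXR) with every probe set tested. They turned to 0.0030 (neutrophil, without shared probe sets), to -0.011 (autophagy receptors) and -0.078 (interferon) without dim genes, to -0.0062 (autophagy receptors) after median centring, and to 0.070 (bile acids), 0.019 (CAR and PXR), -0.016 (lymphocyte) and -0.023 (acinar) with array weights. Near-background probe sets limit what small differences show.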

Other observations

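The test in this part of how many genes and lists other splits give was planned before its result was seen; the genes named here were chosen after their values were seen. Each DeltaKlf6 liver had large departures of its own. In the library labelled DeltaKlf6 1, Fos (3.35 above the wildtype mean), Btg2 (3.52), Hilpda, a hypoxia-induced lipid droplet gene (3.36), and Akap12 (3.36) were high, and Nr1i3, which encodes the xenobiotic receptor CAR (-3.36), and Shmt1 of folate metabolism (-3.65) were low. None of these lay as far from wildtype in the other 2 libraries: Btg2 was at 0.68 and -0.10 and Nr1i3 at 0.34 and -0.29.

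The library labelled DeltaKlf6 2 had mitotic genes above wildtype and clock genes displaced in both directions. Mki67 (3.14) and Birc5 (2.77) stood above wildtype, as did the retinoic acid hydroxylase Cyp26a1 (4.60) and the clock activator Arntl (3.11). The clock output Dbp (-2.40), Tef (-2.15), Per3 (-2.68) and the phosphatidate phosphatase Lpin1 (-3.62) lay below. In the library labelled DeltaKlf6 3 the highest departures were genes such as Nme5 (2.63) and Corin (2.09), and the lowest included Mex3c (-2.96), Lgr4 (-2.82), Pbrm1 (-2.63) and Suz12 (-2.53), in the array whose control probe sets also stood apart.

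Splitting the 6 arrays 3 against 3 in each of 10 ways gave at least as many genes past adjustment as the real split (0) in 10, the highest other count being 1. With a real count of 0 this was bound to hold, so no conclusion is drawn from it. At an unadjusted p under 0.05, 7 of 10 splits gave at least the real 631 genes and the highest other gave 1533, in the split that sets wildtype 1, wildtype 3 and DeltaKlf6 3 against the rest. For lists past camera at the preset correlation, 9 of 10 splits gave at least the real 6, and the highest other gave 12, in that same split. With 10 splits no share under 0.05 can be reached. Each other split keeps part of the genotype contrast, with 2 of 3 arrays of a genotype on the same side.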
